A study of Mus musculus with 8 samples.

How the data were processed

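Stranded mRNA libraries of cultured hepatocytes from Srsf3-floxed mice, 4 infected with AAV-Cre and 4 with AAV-GFP, were sequenced as paired ends, per the labels' protocols. The labels give 150 cycles, while run names inside 1 deposited file point to 100, and this was left open. Per the submitters' processing notes, FastQC and STAR were used with the genome build mm10; the roles and versions are not given in the sources used here. Replicate numbers come from the labels. Where nothing says that libraries came from separate animals, p-values of the authors may measure technical spread.

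The first deposited table holds local splicing variations, sets of junctions that share an exon, in the column layout of VOILA, the report of MAJIQ, per the file headers. It gives the authors' expected PSI per junction and group, as a fraction, and the expected change. The deposited change correlated at 0.996 with AAV-GFP minus AAV-Cre PSI, so its sign was turned to AAV-Cre minus AAV-GFP. The second deposited table was made with JUM and lists events at p below 0.05, with p-values, q-values and change in PSI as AAV-Cre minus AAV-GFP, per the file headers. In it 63 of 498 events had no finite change and 48 had no gene name. Versions and settings of both tools are not given in the sources used here. Neither table holds values per library, so depth and replicate spread are unknown.

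The column of the first table headed as the probability of a change of at least 0.2 does not behave as named. All 4155 junctions with a change under 0.02 had values of 0.95 or more there, and the 32 junctions higher in AAV-Cre by 0.8 or more had values of 0.000795 or less. The rule fixed before the data were examined (probability of at least 0.95 with a change of at least 0.2) was kept, and it called the same 821 variations as the change alone. The column of de novo junctions was 0 throughout, so junctions absent from GENCODE vM21 were left out instead as an added alternative. In the second table, events were called at a q-value of 0.05 or less and a change of at least 0.1.

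Variations of 2 junctions were sorted into cassette exons, retained introns and alternative splice sites from their coordinates and GENCODE vM21. A further 29 changed variations that joined 2 exons with no cassette exon found, as alternative first or last exons do, were kept apart, and the rest were called complex. A binary exon or intron listed more than once was counted once, with the larger change. Complex variations, added only as an alternative, were counted per variation, so an exon or intron could enter more than once. Their direction was that of the intron part, or the reverse of that of the most distant junction, with no size threshold on that part. Directions were tested with exact two-sided binomial tests against 0.5. Exon properties were tested on the changed cassette exons of both tables together, a choice made before those results were seen, with two-sided permutation tests of 100000 resamples and Fisher's exact test. Sequences came from vM21 transcripts and covered 68 of 72 exons (94.4%), and motif density used exons of at least 20 nt. No genome sequence was used here. Windows of 100 kb with 8 or more listed variations were called dense. On simulated data, classes and directions were recovered in 100% of 400 variations, and directions in 100% of 200 splice site events. These variations were all binary, with every cassette exon annotated. Complex variations and alternative first or last exons were not simulated, so their sorting was not checked. The permutation test, with fewer resamples and exons of random bases, called 3.0% of 1000 simulated comparisons without a motif difference.

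The gene lists were fixed before the data were examined: SR proteins and related factors, hnRNPs and other splicing regulators, core spliceosome, RNA decay, insulin and growth factor signalling, lipid, cholesterol and bile acid metabolism, glucose and glycogen metabolism, hepatocyte transcription factors, plasma proteins, drug metabolism, cytoskeleton, adhesion and matrix, cell cycle and repair, chromatin regulators, circadian clock, mitochondria, autophagy and traffic, neddylation and ubiquitin, antiviral response, markers of 5 other cell types, and genes linked earlier to SRSF3 in liver. Fisher's exact test of lists ran only within the junction-usage table, whose background is itself limited to p below 0.05; local variations were counted only. Named genes were fixed by rule: Srsf3; the 12 genes with the largest changes among changed cassette exons, 5 among introns and 3 each among 5' and 3' splice sites (1 binary event per gene); up to 4 per list; and Fn1, Slk and Insr. A further gene of this rule is not reported here. Alternatives changed the thresholds, the events counted, the motifs and the treatment of dense windows and overlapping genes. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.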

Results

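Hepatocytes, the main parenchymal cells of the liver, were taken from mice of the C57BL/6J strain that carried floxed Srsf3 alleles and were kept in culture. They were infected for 48 h with an adeno-associated virus (AAV) that expressed either Cre recombinase, which removes the floxed part of Srsf3, or green fluorescent protein (GFP). SRSF3 is an SR protein, an RNA-binding regulator of splicing. There were 4 AAV-Cre and 4 AAV-GFP libraries of stranded mRNA. The measurements were percent spliced in (PSI, on a scale of 0 to 1) for each group and its change, AAV-Cre minus AAV-GFP. Both tables held 1 value per group or comparison, so the spread between libraries and the depth of each library are unknown, and no SD is given. The tests below count events and measure the spread over events, not over cultures.

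The first comparison concerned Srsf3 itself, which checks the labels. In the authors' deposited table of local splicing variations, the junction from exon 1 to exon 2 of Srsf3 (chromosome 17, 29032786 to 29036241, mm10) had a group PSI of 0.998 in AAV-GFP and 0.157 in AAV-Cre. In the same authors' deposited table, the junction from exon 1 to the exon that starts at 29040775, which skips exons 2 and 3, went from 0.001 to 0.767. The exon at 29039454 to 29039909, annotated in transcripts subject to nonsense-mediated decay, was joined from exon 3 at a PSI of 0.995 in AAV-GFP and 0.006 in AAV-Cre in the authors' deposited table. These values are shares of the junctions that enter this exon, among which its junction from exon 1 had 0.005 and 0.994 in the authors' deposited table. Among the junctions that leave exon 1, as for the first 2 junctions above, it had 0.001 and 0.078 in the authors' deposited table. In the authors' deposited table of junction usage, Srsf3 was listed as a composite event with a q-value of 2.38e-05 and a largest change of 0.889. The local variations thus gave the libraries labelled AAV-Cre a high usage of junctions that bypass exons 2 and 3.

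**Figure D1:**
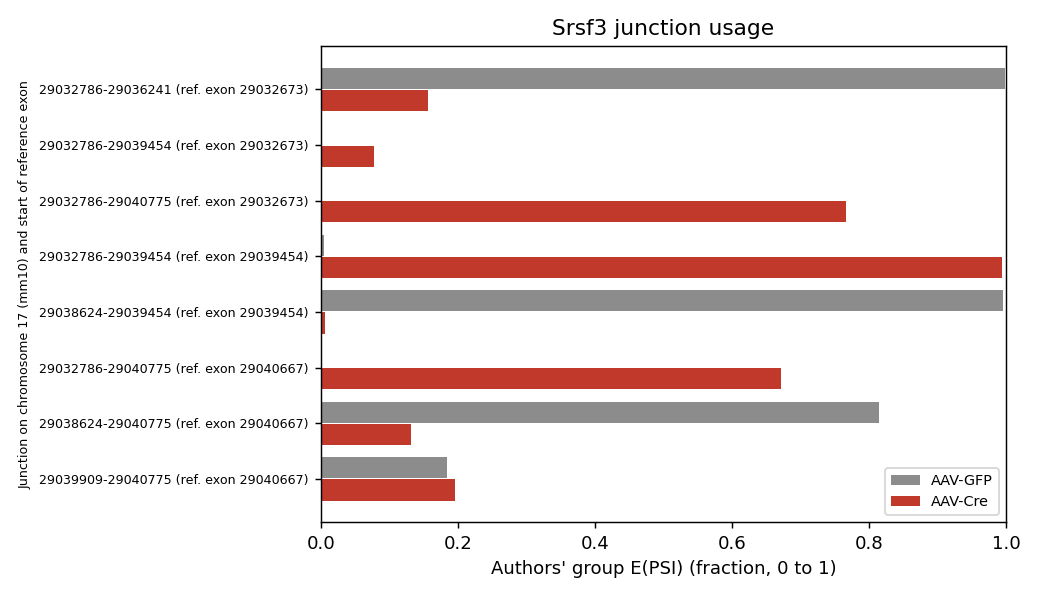
Usage of each listed Srsf3 junction on chromosome 17 (mm10), as the authors' deposited group PSI from 0 to 1, in AAV-GFP (grey bars) and AAV-Cre (red bars). The junction from exon 1 to exon 2 falls from 0.998 to 0.157.

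The second comparison asked how many splicing variations differed between AAV-Cre and AAV-GFP. The authors' deposited table of local splicing variations listed 862 variations in 354 genes, of which 821 had a junction that changed by at least 0.2. Of the 862, 423 lay in 3 windows of 100 kb. The densest of these windows, on chromosome 9 from 3000001 to 3100000, held 397 variations of 10 genes such as Gm26870. Without these windows 438 changed variations were left, of 439 listed there. All 354 listed genes had a changed variation. The list thus seems to hold variations that had already been chosen for a change. The 821 of 862 is therefore not a share of all measured variations. Of the 821, 660 were complex and entered the tests of direction only as an alternative. The authors' deposited table of junction usage listed 498 events at p below 0.05. Of these, 73 had a q-value of 0.05 or less and 57 also had a change of at least 0.1. The probability column of the first table did not behave as its header names it, and the size of the change alone gave the same 821 calls.

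Cassette exons changed in both directions after Cre, and the excess of less included exons did not pass the test. Dpp7, a lysosomal dipeptidyl peptidase, lost exon 9 (chromosome 2, 25353608 to 25353726). The PSI of this exon was 0.954 in AAV-GFP and 0.162 in AAV-Cre in the authors' deposited table. Exon 17 of Clcn7, a lysosomal chloride transporter (chromosome 17, 25155368 to 25155537), went from 0.996 to 0.290 in the authors' deposited table. An exon of 12 nt in Supt5, a transcription elongation factor, went from 0.881 to 0.253, and exon 10 of Nadk, an NAD kinase, from 0.988 to 0.457, in the authors' deposited table. The authors' deposited table also gave lower inclusion of a 5' UTR exon of Klhdc3 (0.993 to 0.475; also listed under the overlapping Gm26904) and of exon 24 of Bag6, a chaperone (0.752 to 0.247). Xpnpep1, an aminopeptidase, gained its exon 2, from 0.229 to 0.770 in the authors' deposited table. The same exons changed, by junction usage, by -0.540 in Supt5 (q = 0.0172) and -0.446 in Nadk (q = 0.000646) in the authors' deposited table. Those of Dpp7 (-0.433, q = 0.186), Clcn7 (-0.539, q = 0.108) and Klhdc3 (-0.416, q = 0.518) did not pass in the authors' deposited table. The exons of Bag6 and Xpnpep1 had no match by coordinates there.

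By junction usage, the authors' deposited table gave changes of -0.643 for exon 19 of Smc5, a chromosome maintenance protein (q = 0.00955), and of -0.533 for exon 18 of Mta1, a chromatin remodelling subunit (q = 0.0124). Exon 3 of the transcription factor Mlx changed by -0.509 (q = 0.00444) in the authors' deposited table. An exon of 21 nt in Afdn, a junction protein, changed by 0.589 (q = 0.00489) in the authors' deposited table. An exon of 13 nt in 2010111I01Rik that is not annotated changed by 0.540 (q = 0.0276) in the authors' deposited table. Over all changed binary cassette exons, 22 were higher and 38 lower by local variations (exact two-sided binomial p = 0.0519), and 5 were higher and 11 lower by junction usage (exact p = 0.210). With a size of at least 0.3, 16 were higher and 15 lower by local variations. With 1 event per gene the counts stayed at 22 and 38. Fip1l1 and Picalm, with more than 1 exon each, then entered once each. An exon listed under more than 1 gene, such as that of Klhdc3 and Gm26904, entered once per gene. That alternative is therefore a count of gene symbols and can hold the same exon more than once. With complex variations added the direction turned, with 316 higher and 222 lower (exact p = 5.85e-05), and without the dense windows it was 94 higher and 144 lower (exact p = 0.00144), an alternative chosen after seeing the data. A complex variation was counted by its most distant junction, whatever the size of the change there, and an exon could enter more than once. These are therefore not counts of separate exons that changed by at least 0.2.

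**Figure D2:**
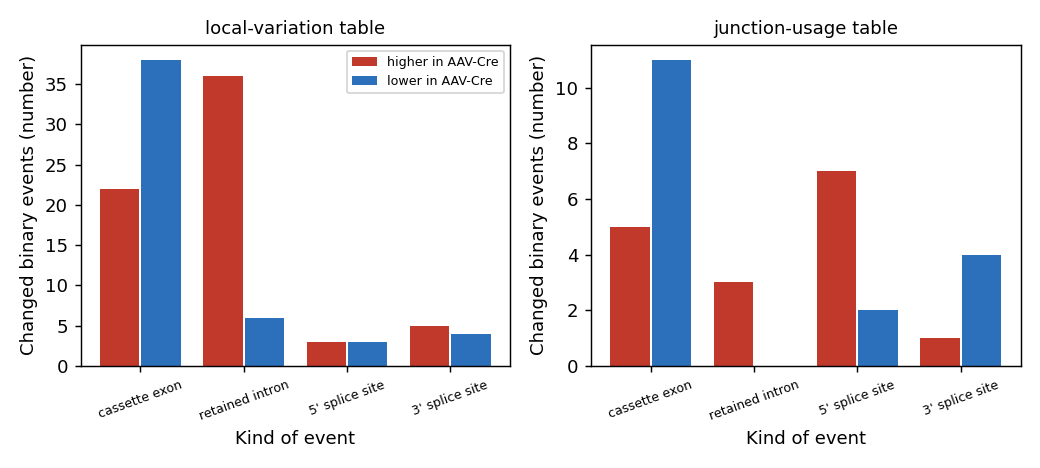
Number of changed binary events per kind that were higher (red) or lower (blue) in AAV-Cre, in the table of local splicing variations (left) and of junction usage (right). Of the introns in the left plot, 36 are higher and 6 lower.

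Introns were mostly more retained after Cre. Ermard, named for a role in RNA degradation at the endoplasmic reticulum membrane, retained an intron of 375 nt (chromosome 17, 14987699 to 14988073) at a PSI of 0.044 in AAV-GFP and 0.925 in AAV-Cre in the authors' deposited table. An intron of 134 nt in Retsat, a retinol saturase, went from 0.078 to 0.692 in the authors' deposited table. An intron of 82 nt in Cox20, a cytochrome c oxidase assembly factor, went from 0.232 to 0.873 in the authors' deposited table, but it overlaps an exon of Hnrnpu on the opposite strand. In the authors' deposited table the retained introns with the largest changes also included Gm10722 (0.994 to 0.004) and Gm26870 (0.164 to 0.884), both in the dense window of chromosome 9. Of 42 introns, 36 were more and 6 less retained in AAV-Cre (exact two-sided binomial p = 2.83e-06). Outside the dense windows 32 of 34 were more retained, and the 2 exceptions, named after their values were seen, were Srsf5 and Paip2b. With complex variations added, 132 of 199 intron parts were higher and 67 lower (exact p = 4.75e-06). An intron could enter this count more than once, and at any size of its own change, so the p-value does not rest on independent events. Of the 34 introns, 12 overlap an exon of another gene, 11 of them on the opposite strand. By junction usage, the 3 changed introns (Hcfc1r1, Ilk and Coro1b, named after their values were seen) were all more retained, where an exact test cannot go below p = 0.25. The intron of Ilk overlaps an exon of Taf10 on the opposite strand. At the authors' p threshold with a size of 0.1, chosen after seeing the data, 7 were more and 5 less retained by junction usage (exact p = 0.774).

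Alternative splice sites showed no direction that passed the test. At 5' splice sites, Ggnbp2 used the exon-lengthening site at a PSI of 0.399 in AAV-GFP and 0.810 in AAV-Cre in the authors' deposited table. The authors' deposited table of junction usage gave changes of 0.642 for Dsp, a desmosomal protein (q = 0.00310), and 0.606 for Clcn7 (q = 0.00464). At 3' splice sites, the exon-lengthening site of Tma16 went from 0.428 to 0.022 and that of Gm43545 from 0.868 to 0.361 in the authors' deposited table. Azin1, an antizyme inhibitor, changed by -0.400 (q = 0.00904) in the authors' deposited table. By local variations 3 of 6 5' sites and 5 of 9 3' sites were lengthening (exact p = 1 for both). The same pair of sites (chromosome 14, 54646833 to 54646836) was counted as lengthening in both, under Gm17606 at 5' and Acin1 at 3' sites. These genes were named after their values were seen. By junction usage 7 of 9 5' sites (exact p = 0.180) and 1 of 5 3' sites (exact p = 0.375) were. Of the pairs of sites by junction usage, 2 of 9 and 2 of 5 lay within 1 annotated exon, so the other pairs can join different exons.

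The changed cassette exons of both tables together were 72, of which 46 were lower and 26 higher in AAV-Cre. Lower exons were longer, with a median of 113 nt against 66.5 nt. The difference in mean log2 length was 0.66 (permutation p = 0.0106, two-sided), and at a size of at least 0.3 it was 0.52 and did not pass (permutation p = 0.163). Exon lengths divisible by 3 were found in 31 of 46 lower and 16 of 26 higher exons (Fisher's exact p = 0.618). The GC content was 51.9% ± 10.4 (SD over 45 exons) in lower and 47.2% ± 7.81 (SD over 23 exons) in higher exons (permutation p = 0.0644), and the difference passed with 1 event per gene (permutation p = 0.0419). The SRSF3 motif WCWWC occurred 0.903 ± 1.18 times per 100 nt (SD over 44 exons) in lower exons. In higher exons it occurred 0.589 ± 0.859 times (SD over 23 exons), a difference that did not pass the test (permutation p = 0.262) but did at a size of at least 0.3 (permutation p = 0.0482). The SRSF3 motif CATC did not pass either, at 0.525 and 0.296 times per 100 nt (permutation p = 0.187). A further SRSF3 motif, CHWCHMC, occurred 0.789 ± 1.18 times per 100 nt in lower exons (SD over 44 exons). In higher exons it occurred 0.0729 ± 0.247 times (SD over 23 exons; permutation p = 0.00066; Benjamini-Hochberg adjusted p = 0.0033 over 5 motifs). Only 20 of the 44 lower and 2 of the 23 higher exons held this motif at all.

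The 2 tables were made from the same libraries, so their comparison checks orientation only. By coordinates 25 events changed by local variations were also listed by junction usage at p below 0.05, of which 24 had the same sign in both (exact p = 1.55e-06). Only 5 of the 25 passed the thresholds of both tables, and these 5 had the same sign. The exception was an exon of Axin1, named after its values were seen. Across these events, which are not independent replicates, Pearson's r was 0.916 and Spearman's rho 0.863. Of 354 genes called by local variations, 130 were among the 414 genes listed by junction usage.

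**Figure D3:**
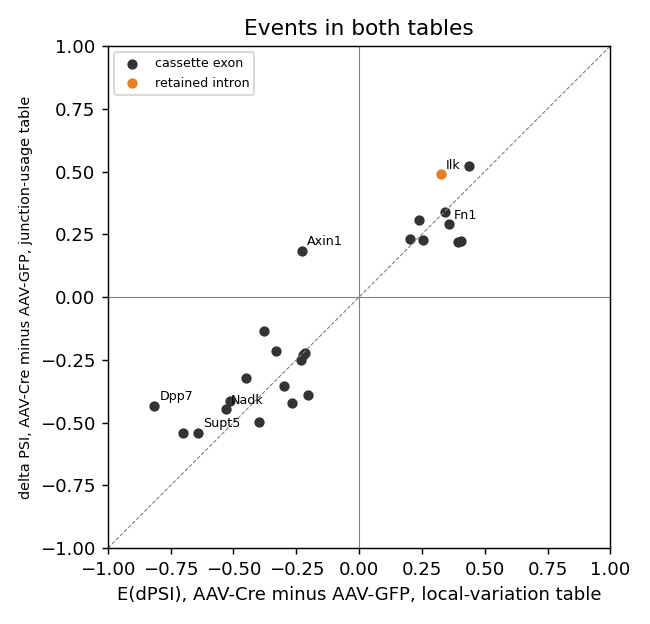
Change in PSI of each event found in both tables, AAV-Cre minus AAV-GFP, by local variations (x axis) and junction usage (y axis), with the identity line dashed. Of 25 events, 24 have the same sign, and Axin1 does not.

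Splicing regulators were among the changed genes. Of 38 SR proteins and SR-related factors, 8 had a changed event in either table, and 1 of these is Srsf3, the floxed gene itself. Within the genes listed by junction usage this list did not pass (Fisher's exact p = 0.326). In the authors' deposited table the most changed junction of Srsf6 went from 0.185 to 0.837 and that of Rsrp1 from 0.887 to 0.367, while retention of an intron of Srsf5 went from 0.816 to 0.416. Of 61 hnRNPs and other regulators, 10 changed, with exons of 1 gene higher and of 4 lower. The most changed junction of Hnrnpu went from 0.035 to 0.656 and that of Pcbp2 from 0.399 to 0.885 in the authors' deposited table. The junction of Pcbp2 bypasses an exon (chromosome 15, 102485948 to 102486040). By junction usage this exon changed by -0.351 (q = 0.00965) in the authors' deposited table. A higher PSI of a most changed junction thus need not mean more inclusion of an exon. By junction usage Hnrnpl had an exon that changed by 0.426 (q = 0.0146), and Hnrnpr a composite event with a largest change of 0.390 (q = 0.00308), in the authors' deposited table. Core spliceosome genes changed in 2 of 53 cases. Slu7 went from 0.282 to 0.064 at its most changed junction, and U2af2 changed by 0.137 at a 3' splice site (q = 0.000312), in the authors' deposited table. Of 35 genes of RNA decay only Cnot2 changed, from 0.257 to 0.046 in the authors' deposited table. Its junction ends at an exon (chromosome 10, 116537221 to 116537278) that the authors' deposited table also listed, at 0.256 and 0.036, under 5330438D12Rik, a gene that overlaps Cnot2.

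Of 59 genes of insulin and growth factor signalling 3 changed: the most changed junction of the phosphatase Ptpn11 went from 0.644 to 0.239, an exon of Shc1 from 0.946 to 0.717 and a 3' splice site of Mapk9 from 0.131 to 0.368 in the authors' deposited table. Of 76 lipid and bile acid genes 2 changed. Retention of an intron of Acadvl, a fatty acid oxidation enzyme, went from 0.014 to 0.477 in the authors' deposited table, at a place that overlaps an exon of Dvl2, and a junction of Hadhb went from 0.354 to 0.041. Of 49 glucose and glycogen genes 4 changed, and their most changed junctions in the authors' deposited table were G6pdx (0.180 to 0.816), Pkm (0.279 to 0.850), Khk (0.644 to 0.890) and Creb1 (0.993 to 0.735). Of 34 hepatocyte transcription factors 2 changed, Yap1 (0.784 to 0.325) and Nfe2l1 (0.915 to 0.630), at their most changed junctions in the authors' deposited table. Of 39 plasma protein genes 2 changed, Itih1 (0.978 to 0.678) and Rbp4 (0.201 to 0.452), also at their most changed junctions in the authors' deposited table.

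Of 82 genes of the cytoskeleton, adhesion and matrix 8 changed. The most changed junction of Cttn, an actin-binding protein, went from 0.104 to 0.790, that of the dynamin Dnm2 from 0.102 to 0.670 and that of Myo9b from 0.475 to 0.058, and an exon of 27 nt in the kinase Mark3 from 0.978 to 0.501, in the authors' deposited table. Membrane traffic and mitochondrial genes changed in 7 of 59 cases. These included, in the authors' deposited table, exons of Sec31a (0.989 to 0.592) and Picalm (0.506 to 0.194), and junctions of Dnm1l (0.566 to 0.898) and Atg16l1 (0.526 to 0.855). Of 68 chromatin regulators 3 changed. Their most changed junctions in the authors' deposited table were those of Brd8 (0.2 to 0.625), Kdm1a (0.523 to 0.2) and Brd2 (0.996 to 0.730). Of 61 cell cycle and repair genes Ccnl1 changed, with an exon at 0.409 in AAV-GFP and 0.830 in AAV-Cre in the authors' deposited table. Of 34 antiviral genes Oasl1 changed, with intron retention at 0.623 and 0.894 in the authors' deposited table. None of 33 drug metabolism, 20 circadian and 37 neddylation and ubiquitin genes were called at these thresholds. By junction usage, 3, 0 and 5 of them were listed at p below 0.05.

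Among markers of other liver cells, 1 of 15 Kupffer cell and macrophage genes changed, Cd68, from 0.975 to 0.779 at its most changed junction in the authors' deposited table. No call was made in the lists of 14 stellate cell, 13 endothelial, 10 cholangiocyte and 11 lymphocyte genes. Of the genes linked earlier to SRSF3 in liver, Fn1 and Srsf3 changed. Exon 33 of Fn1, fibronectin (270 nt; chromosome 1, 71603660 to 71603929), went from 0.106 to 0.453 in the authors' deposited table, and by junction usage it changed by 0.291 (q = 0.0291). Exon 13 of Slk had a change of -0.340 in the authors' deposited table, with q = 0.318. Insr was not listed as changed in either table. Over 23 lists, tested within the genes listed by junction usage at p below 0.05, 2 had an unadjusted p below 0.05 in Fisher's exact test. These were hnRNPs and other regulators (exact p = 0.0152; Benjamini-Hochberg adjusted p = 0.350) and the genes linked earlier to SRSF3, which include Srsf3 itself (exact p = 0.0366; adjusted p = 0.421), so no list passed after adjustment. Of the 23 lists, 5 had no listed gene, and 10 in all held too few for an unadjusted p below 0.05. Over the other 13, a choice made after seeing the data, the smallest adjusted p was 0.198.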

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

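Alternatives named here as added were chosen after seeing the data. Of 114 recomputed values, 54 were set aside. Of these, 10 rest on the probability column and 19 equal the main value, some on other events. In 25, the main value or the alternative has too few events for an exact p below 0.05. Of the other 60, 39 kept their direction and side of the threshold, or stayed within 1.5 times a count. The excess of introns more retained in AAV-Cre by local variations passed in all 9 of its alternatives among these, at 66.3% to 94.3%. The lowest share is that with complex variations added. Complex variations were counted per variation, whatever the change of their exon or intron part, so an exon or intron could enter more than once. The 821 changed local variations became 489 at a size of 0.3, 354 counted as genes and, as added alternatives, 438 without dense windows and 237 without junctions absent from the annotation. The 57 events by junction usage became 33 at an FDR of 0.01 and, as added alternatives, 36 at a size of 0.3, 28 without junctions absent from the annotation and 498 at the authors' p threshold alone, with no q-value or size threshold. The share of cassette exons higher in AAV-Cre by local variations (36.7%) turned to 51.6% at a size of 0.3 and to 58.7% with complex variations, which passed in the opposite direction (exact p = 5.85e-05). It passed as an excess of lower exons at 35.3% with source and target counted, and as added alternatives at 34.5% without Mup, Serpina1 and H2 genes and at 39.5% with complex variations but no dense windows. Splice site shares rest on few events: by local variations 3' sites (55.6%) came to 50% at a size of 0.3 and, as an added alternative, without junctions absent from the annotation, and 5' sites (50%) to 100% of 1 site at a size of 0.3. By junction usage 3' sites (20%) came to 50% of 2 sites within 1 annotated exon, an added alternative. At a size of 0.3 the log2 length difference was 0.52 and no longer passed (permutation p = 0.163), the WCWWC difference was 0.792 (permutation p = 0.0482) and list genes fell from 55 to 35. The motif difference was 0.716 with CHWCHMC, which passed, 0.229 with CATC and -0.827 with the control motif GWWGW, which did not. The GC difference passed the threshold at 5.05 points with 1 event per gene (permutation p = 0.0419) and, as an added alternative, at 5.28 at the authors' p threshold (permutation p = 0.00244). The cause was not tested. Probability thresholds of 0.90 and 0.99 left 821 and 819 local variations and the same counts of direction, since that column hardly filters. Motifs in intron flanks were not run, and complex splice site variations of the local-variation table gave no direction. No paired analysis was possible because the tables hold no values per library, although the labels number both groups 1 to 4; leaving out single libraries was not possible for the same reason.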

Other observations

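The tests of overlapping genes, of the other tool's introns and of repeat junctions were chosen only after the results were seen.

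Binary introns by local variations were mostly more retained in AAV-Cre, in 36 of 42 cases and in 32 of 34 outside dense windows. Reads of overlapping genes do not account for the whole pattern, since 90.9% of the 22 introns without overlaps and outside dense windows were higher (exact p = 0.000121). A general rise of unspliced RNA or genomic DNA remains open: where another junction changed most, the intron part was higher in 72.5% of 80 variations (exact p = 7.01e-05), which loss of SRSF3 could also give. By junction usage, introns were taken here at p below 0.05 and a change of at least 0.1, with no q-value threshold. Of 9 named ones outside dense windows 77.8% were higher. Against them stood 94.1% of 34 by local variations, called at a change of at least 0.2 (Fisher's exact p = 0.188). With unnamed introns it was 7 of 11 (Fisher's exact p = 0.0247), and over all introns 7 of 12 against 36 of 42 (Fisher's exact p = 0.0526). Both sides come from the same libraries and share the intron of Ilk, so they are not independent. An effect of 1 tool therefore stays open, as the thresholds differ and the call turns on few unnamed introns. Effects of Cre or GFP themselves are confounded with the loss of SRSF3.

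A large part of the local variations, 423 of 862, lay in 3 windows. In these windows 2.08% of 2939 junctions were in the annotation, against 71.8% of 1199 elsewhere, which is consistent with reads shared between copies of a repeat. Junctions listed under more than 1 gene made up 44.3%, between the bounds set for overlapping gene models, so that part stays open. A change in repeat RNA between the groups was not tested.

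Exons lower in AAV-Cre held more CHWCHMC motifs per 100 nt, 0.789 against 0.0729. The motif was present in 20 of 44 lower and 2 of 23 higher exons, so the higher mean rests on few exons in each group. Base composition does not account for the whole difference of 0.716: beyond 200 shuffles of each exon's own bases, 0.451 per 100 nt remained (permutation p = 0.00478), so part of it may go with composition. The planned main motif WCWWC and the motif CATC did not pass, and binding of SRSF3 to these exons was not tested.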
